A study of Mus musculus with 6 samples.

How the data were processed

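RNA of primary mouse dermal fibroblasts was measured in 6 libraries, 2 each of control cells (floxed Yap1 and Wwtr1, no Cre), YAP/TAZ KO cells (the same floxed alleles with a tamoxifen-dependent Cre from ROSA26) and YAP/TAZ KO cells given 1 µM H-151. All were cultured for 72 hr with 1 µM 4-hydroxytamoxifen, per the labels' protocols, which spell the inhibitor once as H-15. Libraries were made with the QuantSeq 3' mRNA-seq method, per the labels' protocols. STAR 2.5.3a, featureCounts, edgeR and the mm10 genome build are listed in the submitters' processing notes, which give neither the gene annotation, nor the strand setting of the counting, nor any filter on low genes.

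The deposited table holds 1 value per gene symbol and library for 13706 genes, with 3 decimals, and all 6 columns were used. All 13706 genes reached 0.5 in at least 2 libraries. The deposited values are a scaled signal, CPM computed with an effective library size. In each column all values were whole multiples of 1 step within a tolerance of 0.0006, and the columns summed to different totals, from 955838 to 1083570. The plan written for plain CPM was kept for this unit, since the log2 transformation and test apply to it equally, and values are called scaled CPM throughout. Dividing by the step recovered whole reads, 100.0% of them exact in a simulation. The libraries held 12444986 to 15308100 reads in the listed genes, with a median of 246 to 336 reads per gene, and 1 read equals 0.0625 to 0.0871 scaled CPM.

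Values were transformed to log2(scaled CPM + 1). Genes with at least 1 scaled CPM in at least 2 libraries were tested (13648 genes; 58 were not). A linear model with 1 mean per group was fitted with limma 3.58.1 in R 4.3.3, with moderated variances that follow a trend with mean level (3 residual degrees of freedom, 15.7 after moderation). P-values were adjusted with the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. The comparisons were KO against control, KO + H-151 against KO, and KO + H-151 against control. Fold changes on this scale understate the change of genes with low levels. For genes with 0 reads in a group, the fold is given as a bound against a floor of 3 reads over the group, and for genes with 1 to 3 reads as the ratio of reads with its interval; such bounds and intervals cover counting error only. Genomic positions are those of the GRCm38 assembly, the same build as mm10.

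Gene lists, tests, alternatives and the rule for named genes were fixed before the data were examined. Of 37 gene lists, 34 had at least 5 tested members, and 11 genes stood in 2 or more lists. Lists were tested with camera on the moderated t-statistics with a preset correlation between genes of 0.01, with an estimated correlation and fry, a rotation test, as alternatives. Of 41 list calls in the 3 comparisons, 0 held with an estimated correlation (lowest adjusted p = 0.105). With it 17 list tests had an unadjusted p under 0.05, and fry called 68, without 3 of the 41. The test with an estimated correlation rests on the 3 residual degrees of freedom. A call lost there is therefore no sign by itself that members move together. The NRF2 antioxidant list in KO + H-151 against control had an estimated correlation of -0.0464. Its unadjusted camera p still went from 2.88e-12 with the preset correlation to 0.00945. For each of these lists described the count of members past the threshold is given over all genes and, where it differs, with p-values adjusted over the list alone. Named genes are, per comparison, the 12 with the largest rise and the 12 with the largest fall. These are taken from genes past the threshold whose groups do not overlap and whose higher group has a mean of at least 5 scaled CPM, without unnamed gene models, clones, mitochondrial genes and pseudogenes. For each list described, up to 4 members are named, the 3 with the smallest p and the 1 with the highest mean. Named too are 16 genes chosen in advance and the 10 genes with the largest sum of absolute changes past both KO and H-151 tests. Other genes are marked as chosen after their values were seen, and a few genes that the rule or a count would name are not reported here.

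The correlation between the KO and H-151 effects, which share the KO libraries, was set beside 100 simulations of unchanged groups. Alternatives were pseudocounts of 0.25 and 4, no filter, a filter on a mean of 10 scaled CPM or more, median scaling, quantile normalization and a fit of only the groups compared. Further alternatives were no trend in the prior variance, a term for the replicate number, each library left out in turn, edgeR 4.0.16 (quasi-likelihood, TMM) and DESeq2 1.42.0 on the recovered reads, and a 2-fold minimum change. Added after seeing the data were total-count scaling, a crossed replicate term and the overlap with the KO libraries split between the 2 effects. Added too was the overlap without the 54 members of the interferon-stimulated list. This left 1799 genes higher in KO and lower with H-151, 1179 the other way and a correlation of -0.84. Interferon-inducible genes outside the list, such as Cxcl9 and Gbp5, stayed in, so an overlap free of interferon-inducible genes was not tested. The tests were tested on simulated reads with 200 changed genes, as many up as down, drawn from genes with a mean of at least 5 scaled CPM. For KO against control, limma called 84.8% of genes changed 1.5-fold, 97.2% of those changed 2-fold and 100% of those changed 4-fold. Of the calls, 6.37% were false (5 simulations, 13396.2 genes on average). These shares do not cover genes with lower levels. They also need not hold in the data, where 4421 genes were called for KO against control. Tables and figures were made with Python 3.11.15, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.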

Results

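Messenger RNA of primary mouse dermal fibroblasts was measured by QuantSeq, a tag method that reads the 3' ends of polyadenylated transcripts, in 6 libraries that formed 3 groups of 2. Control cells carried floxed alleles of Yap1 and Wwtr1 and no Cre recombinase. YAP/TAZ knockout (KO) cells carried the same floxed alleles and a tamoxifen-dependent Cre expressed from the ROSA26 locus. The remaining group held KO cells that also received 1 µM H-151, a small-molecule inhibitor of STING. All cells were cultured for 72 hr with 1 µM 4-hydroxytamoxifen. Yap1 encodes YAP and Wwtr1 encodes TAZ, transcriptional coactivators that the Hippo pathway restrains. STING is the adaptor protein that turns the sensing of cytosolic DNA by cGAS into an interferon response.

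The libraries held 13505502 and 13460716 reads in the listed genes for control, 12444986 and 12695418 for KO, and 14630747 and 15308100 for KO + H-151. Levels of 13706 genes were given as reads scaled to library size (scaled CPM), and 13648 genes were tested. Replicate libraries had Spearman correlations across genes of 0.995 in control, 0.996 in KO and 0.994 in KO + H-151. The correlation of control with KO libraries was 0.952 to 0.953, that of KO with KO + H-151 libraries 0.940 to 0.942, and that of control with KO + H-151 libraries 0.980 to 0.983. The first principal component, with 76.1% of the variance, set the KO libraries apart from the other 4. The labels do not say whether the 2 libraries of a group came from separate cultures or animals, so p-values measure only the spread between these libraries. Levels below are means ± SD of scaled CPM (n = 2 libraries per group), and log2 changes are on the log2(scaled CPM + 1) scale, ± SE. Members in brackets after a count of 5 or fewer were named after their values were seen, and † marks a gene whose call was lost when 1 library was left out.

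The targeted genes were examined first. Wwtr1 (chromosome 3, 57455644 to 57575910, GRCm38) fell from 216 ± 3.69 in control to 4.91 ± 0.167 in KO, a log2 change of -5.20 ± 0.13 (adjusted p = 1.55e-14, limma), and stood at 3.54 ± 0.658 in KO + H-151. Yap1 (chromosome 9, 7931999 to 8004638, GRCm38) fell from 125 ± 4.14 to 67.4 ± 1.32 in KO, a log2 change of -0.88 ± 0.08 (adjusted p = 1.34e-07), and to 43.9 ± 2.08 in KO + H-151, -0.61 ± 0.08 against KO (adjusted p = 8.35e-06). In each Cre-bearing library both transcripts lay below both control libraries. The labels do not name the floxed exons, and a 3' tag outside the deleted part of a gene would check nothing, so the remaining Yap1 reads are not a measure of intact transcript.

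The comparison of KO with control asks what the loss of YAP and TAZ changes in fibroblast expression. The interferon-stimulated gene Rsad2, which encodes the antiviral enzyme viperin, rose from 6.50 ± 3.14 to 6408 ± 11.8, and Cxcl10, a chemokine that attracts T cells, rose from 4.78 ± 2.62 to 4695 ± 169. Ifit1, an antiviral RNA-binding protein, rose from 86.5 ± 16.2 to 13402 ± 4.55 and reached the highest level of its list. The antigen presentation gene Tap1 and the chemokine gene Ccl2 rose too, whereas Ccn1, a target of YAP and TAZ, and the endoplasmic reticulum chaperone gene Hspa5 fell.

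Of 54 interferon-stimulated genes tested, 53 rose and 0 fell, over all genes tested and adjusted over the list alone, with a median log2 change of 4.03. The camera adjusted p underflowed to 0, and the adjusted p = 0.131 with an estimated correlation. The member that did not pass was Ifi27l2a, at 0.18 ± 0.26, named after its value was seen. Log2 changes were 9.81 ± 0.21 for Rsad2, 9.75 ± 0.30 for Cxcl10, 8.44 ± 0.20 for Cmpk2, 8.22 ± 0.17 for Mx1 and 7.86 ± 0.16 for Oasl1. They were 7.27 ± 0.16 for Ifit1, 6.77 ± 0.14 for Iigp1 and 6.61 ± 0.20 for Mx2. Adjusted p ran from 1.05e-15 for Iigp1 to 1.61e-13 for Cxcl10. Isg15, a ubiquitin-like modifier, rose from 39.2 ± 4.23 to 1476 ± 36.8 (5.20 ± 0.10, adjusted p = 3.96e-16). Irf7, a transcription factor that amplifies interferon production, rose from 9.88 ± 0.626 to 189 ± 5.26 (4.13 ± 0.12), and Ifih1, which encodes the RNA sensor MDA5, rose from 15.1 ± 0.278 to 726 ± 39.7 (5.49 ± 0.08). Outside the list, the interferon-inducible Cxcl9 rose by 7.84 ± 0.14, Gbp5 by 7.12 ± 0.16 and Ifit1bl1 by 6.51 ± 0.17. The Ifit, Oas, Gbp, Mx and H2 genes have near-identical relatives that share reads, so the split between such members is uncertain.

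Genes of cytosolic DNA sensing, a pathway that can lead to interferon, rose in part. All cells were cultured for 72 hr, so whether these genes rose ahead of the interferon-stimulated genes or along with them was not tested. Of 17 genes of cGAS-STING signalling, 9 rose and 1 fell (11 and 1 adjusted over the list alone), with a median of 0.49 (camera adjusted p = 3.89e-06, adjusted p = 0.282 with an estimated correlation). The member that fell was Trim32, a ubiquitin ligase, at -0.52 ± 0.10, named after its value was seen. Cgas, the sensor itself, rose from 9.99 ± 1.38 to 45.6 ± 4.18 (2.09 ± 0.14, adjusted p = 4.42e-09), and Sting1 rose from 35.9 ± 1.62 to 72.2 ± 8.43 (0.99 ± 0.10, adjusted p = 8.14e-07). Samhd1, an enzyme that breaks down deoxynucleoside triphosphates, rose from 97.9 ± 3.99 to 668 ± 13.97. The kinase Jak1 stood at 532 ± 7.28 and 558 ± 24.5 (adjusted p = 0.513). Ifnb1, which encodes interferon beta and was singled out after its values were seen, had 0 reads in control and 65 reads in KO, at least 26.04-fold higher against a floor of 3 reads over the control group. Setting Ifnb1 to this bound left the list's median at 0.49.

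All 20 antigen presentation genes passed the test: 17 rose and 3 fell, also when adjusted over the list alone, with a median of 1.44 (camera adjusted p = 1.17e-20, adjusted p = 0.268 with an estimated correlation). Tap1, which carries peptides into the endoplasmic reticulum, rose from 25.04 ± 0.0424 to 229 ± 0.00919 (3.14 ± 0.09). The immunoproteasome subunit Psmb10 rose from 25.6 ± 1.40 to 159 ± 9.58 (2.58 ± 0.10) and Nlrc5, the transactivator of MHC class I genes, from 3.76 ± 0.183 to 61.2 ± 2.66 (3.71 ± 0.14). The light chain B2m rose from 1617 ± 177 to 2992 ± 61.02 (0.89 ± 0.09). The members that fell were the endoplasmic reticulum chaperones Calr (-0.78 ± 0.09), Canx† (-0.21 ± 0.07) and Pdia3 (-0.57 ± 0.11), which fold many other proteins as well and were named after their values were seen.

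Of 30 NF-kB targets and secreted inflammatory factors, 20 rose and 3 fell (22 and 3 adjusted over the list alone), with a median of 0.95 (camera adjusted p = 5.43e-15, adjusted p = 0.678 with an estimated correlation). The monocyte chemokine Ccl2 rose from 102 ± 0.761 to 1757 ± 103 (4.09 ± 0.13) and Ccl5 from 2.48 ± 0.781 to 319 ± 6.56 (6.54 ± 0.21). Ccl8 rose from 19.6 ± 0.975 to 139 ± 1.38 (2.77 ± 0.08) and Il6 from 14.5 ± 0.486 to 44.1 ± 7.02 (1.53 ± 0.14, adjusted p = 3.39e-07). The members that fell were the chemokines Cxcl5 (236 ± 49.1 to 28.99 ± 3.44, -2.97 ± 0.26), Cxcl12 (-0.62 ± 0.08) and Cxcl1 (-1.56 ± 0.30, named after its value was seen).

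Targets of YAP and TAZ did not move as a group in the camera test. Of 22 members, 8 rose and 10 fell (9 and 10 adjusted over the list alone), with a median of -0.25 (camera adjusted p = 0.286, adjusted p = 0.703 with an estimated correlation). The fry test, which asks whether the members move one way on balance without reference to other genes, gave an adjusted p = 0.00371. The matricellular gene Ccn1 fell from 307 ± 4.82 to 173 ± 26.6 (-0.83 ± 0.09) and the muscle ankyrin-repeat gene Ankrd1 from 5.73 ± 0.660 to 1.29 ± 0.0205 (-1.55 ± 0.20). Amotl2 fell from 251 ± 2.93 to 98.2 ± 0.961 (-1.35 ± 0.07) and Ajuba from 23.6 ± 0.864 to 9.81 ± 0.578 (-1.19 ± 0.13). Ccn2 stood at 1122 ± 17.4 in control and 977 ± 142 in KO, a log2 difference of -0.21 ± 0.14 that did not pass (adjusted p = 0.265). The receptor kinase Axl rose from 271 ± 8.26 to 448 ± 1.96 (0.73 ± 0.06).

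Of 28 genes of the unfolded protein and integrated stress responses, 4 rose and 16 fell (5 and 16 adjusted over the list alone), with a median of -0.41 (camera adjusted p = 0.0121, adjusted p = 0.782 with an estimated correlation). The chaperone Hspa5 fell from 2439.8 ± 142 to 1422 ± 35.8 (-0.78 ± 0.07) and Ddit4, an inhibitor of mTORC1, from 77.9 ± 2.78 to 28.6 ± 2.21 (-1.41 ± 0.08). The transcription factor Atf3 rose from 14.2 ± 0.829 to 68.4 ± 0.0870 (2.19 ± 0.11). The other members that rose were Trib3†, Slc7a11 and Slc3a2, named after their values were seen. This call was lost without a trend in the prior variance (adjusted p = 0.137) and with fry (0.0894).

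After Wwtr1, the genes with the largest falls in KO were Ppp1r3c, a glycogen-targeting phosphatase subunit, from 27.96 ± 3.87 to 2.23 ± 0.574 (-3.17 ± 0.16), Cxcl5 and Fam43a (-2.72 ± 0.10). The Wnt modulator Dkk2 fell by 2.67 ± 0.16, the lipolysis inhibitor G0s2 from 74.5 ± 6.31 to 11.9 ± 0.308 (-2.55 ± 0.09), the vasodilator peptide gene Adm by 2.24 ± 0.09 and the natriuretic peptide receptor Npr3 by 2.24 ± 0.14. Transcription regulators among the 12 largest falls were Osr1 (-2.16 ± 0.15), Zfp703 (-2.07 ± 0.08) and Id4 (-2.06 ± 0.11). Rps2, a ribosomal protein gene with many processed copies that can share its reads, fell from 423 ± 6.001 to 98.6 ± 2.42 (-2.09 ± 0.07).

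The other 29 of the 34 lists with at least 5 tested members were not past the camera test in KO. Of 25 hypoxia and glycolysis genes, 4 rose and 12 fell (4 and 13 adjusted over the list alone, median -0.25, adjusted p = 0.0880). That list passed under quantile normalization (adjusted p = 0.0193), total-count scaling (0.0411) and fry (0.0313). Of 30 contractile genes, 2 rose and 10 fell (2 and 11 adjusted over the list alone, median -0.06, adjusted p = 0.253), a list that passed under quantile normalization (0.0193). Of 34 mitosis genes, 1 (Cenpe) rose and 11 fell (1 and 16 adjusted over the list alone; median -0.31, adjusted p = 0.0880), a list that passed without control replicate 1 (adjusted p = 0.0463) or KO replicate 1 (0.0176). Of 25 sterol synthesis genes, 13 rose and 0 fell (16 and 0 adjusted over the list alone; median 0.33, adjusted p = 0.205), a list that passed without control replicate 2 (adjusted p = 0.0252). Markers of melanocytes and Schwann cells counted 7 up and 2 (Dct†, Mbp†) down of 11 (median 0.53, adjusted p = 0.0880), and passed under quantile normalization (adjusted p = 0.0337), total-count scaling (0.0411) and fry (0.00600). Of 31 p53 targets, 11 rose and 5 (Btg2†, Gdf15, Perp, Polk†, Sesn1†) fell (11 and 6 adjusted over the list alone), with a median of 0.04 that took the other sign under 2 of the 3 other scalings (lowest -0.13; camera adjusted p = 0.475, fry adjusted p = 0.00600). The largest rise among the p53 targets was that of Tap1 (3.14), which is also in the antigen presentation list. Macrophage markers counted 4 (C1qc†, Ctss†, Fcer1g†, Ptprc) up and 2 (Cd14†, Csf1r) down of 16 (5 and 2 adjusted over the list alone) and adipocyte markers 0 and 2 (Lpl†, Pparg) of 10. Endothelial markers counted 1 (Kdr†) up and 4 (Cdh5, Egfl7†, Emcn, Pecam1) down of 8, with a median of -0.47 (camera adjusted p = 0.253, fry adjusted p = 0.00600). The nuclear lamina gene Lmnb1 stood at 41.7 ± 2.53 in control and 30.3 ± 1.94 in KO (-0.45 ± 0.14, adjusted p = 0.0246). This call was lost without a trend in the prior variance (adjusted p = 0.140) and when any 1 of the 4 libraries was left out (adjusted p = 0.0577 and 0.155 without control replicates 1 and 2, 0.0946 and 0.206 without KO replicates 1 and 2). Actr2, a subunit of the Arp2/3 actin complex, rose from 139 ± 6.39 to 173 ± 3.37 (0.32 ± 0.07), a call lost under quantile normalization (adjusted p = 0.0786), total-count scaling (0.0921) and without a trend in the prior variance (0.0501). The cell cycle inhibitor Cdkn2a rose from 17.2 ± 0.361 to 30.9 ± 1.46 (0.81 ± 0.13). Cdkn1a stood at 775 ± 29.1 and 911 ± 49.6 (0.23 ± 0.07), with the sign reversed under quantile normalization (-0.027) and the call lost without control replicate 1 (adjusted p = 0.123) or KO replicate 1 (0.188), without a trend (0.105) and under total-count scaling (0.424).

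In total, 2483 genes were higher and 1938 lower in KO than in control (limma on log2 values with Benjamini-Hochberg adjustment, adjusted p threshold 0.05), of which 779 and 207 changed at least 2-fold and 63 and 1 (Wwtr1) at least 16-fold. The edgeR quasi-likelihood test on the recovered whole reads gave 2423 and 1851, and DESeq2 2065 and 1217. The count of lower genes was also 1266 with a filter on a mean of 10, 2987 under quantile normalization and 4054 under total-count scaling. The share of higher genes among those changed was 56.2% as deposited, 52.2% under median scaling, 39.1% under quantile normalization and 29.9% under total-count scaling, which moved the median log2 change of all genes from -0.01 to -0.16. The count of lower genes was 1252 and 1171 without control replicates 1 and 2, and 1184 and 1165 without KO replicates 1 and 2. Control and KO cells differ in Cre as well as in YAP and TAZ, so the comparison cannot separate the presence of active Cre from the loss of both genes.

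**Figure D1:**
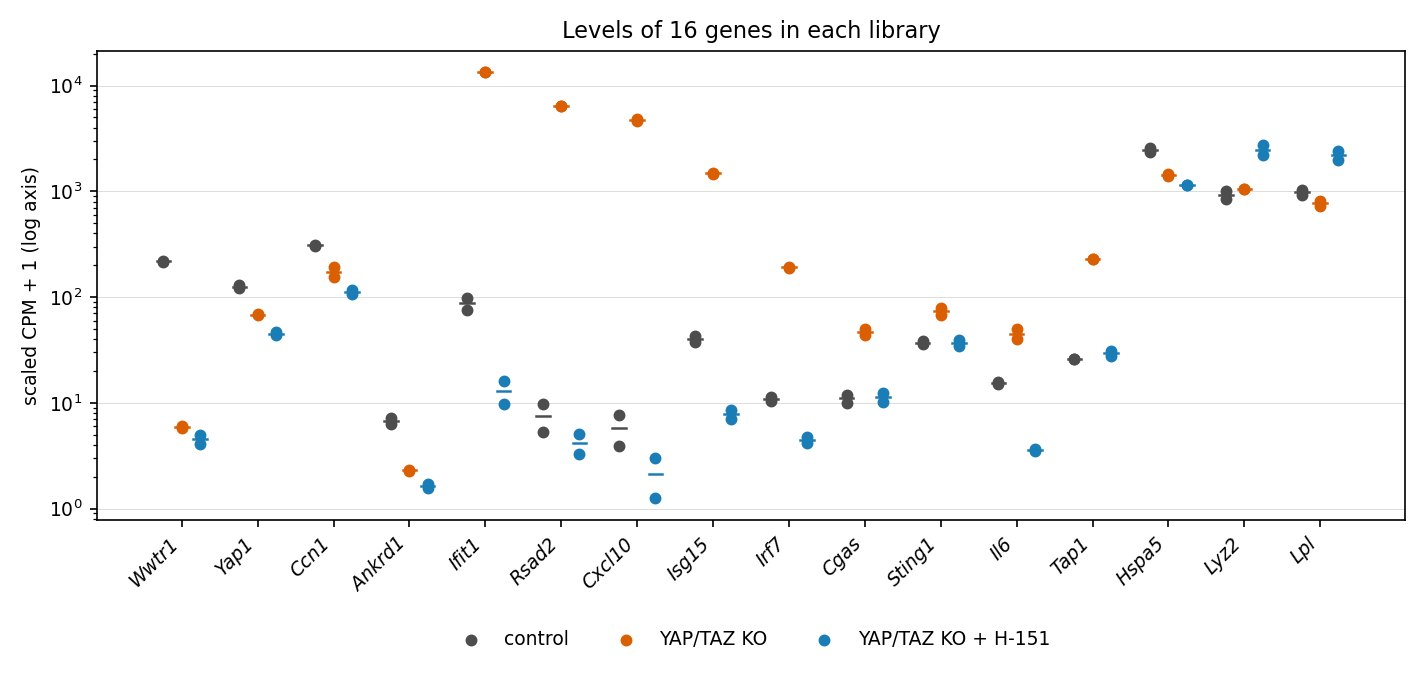
Levels of 16 genes in each of the 6 libraries, as scaled CPM + 1 on a log axis, with a short line at each group's mean (n = 2). Ifit1 stood near 13402 in the KO libraries, against a mean of 86.5 in control and 12.02 in KO + H-151, while Lyz2 and Lpl were highest in the KO + H-151 libraries.

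The comparison of KO + H-151 with KO asks what an inhibitor of STING changes in the YAP/TAZ KO cells. Yap1 stood lower in the KO + H-151 libraries (45.3 and 42.4) than in the KO libraries (66.4 and 68.3). Whether the extent of deletion differed between these groups was not measured. With H-151, 53 of 54 interferon-stimulated genes fell (adjusted p = 0.143 with an estimated correlation), 40 of them below the control level. Rsad2 fell from 6408 ± 11.8 to 3.15 ± 1.27, Ifit1 from 13402 ± 4.55 to 12.02 ± 4.53 and Isg15 from 1476 ± 36.8 to 6.79 ± 1.02. The chemokine gene Ccl2, the antigen presentation gene Tap1, the elastin gene Eln and the immediate early gene Klf4 fell as well. Lyz2, the macrophage lysozyme, rose from 1043 ± 1.78 to 2469.7 ± 382, and Lpl, lipoprotein lipase, from 770.4 ± 58.6 to 2197 ± 291. Hmgcs1 of sterol synthesis and Gstm1 of the antioxidant response rose too.

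Of 54 interferon-stimulated genes, 0 rose and 53 fell with H-151, also when adjusted over the list alone, with a median of -4.98. The camera adjusted p underflowed to 0, and the adjusted p = 0.143 with an estimated correlation. Log2 changes were -11.24 ± 0.30 for Cxcl10, -10.63 ± 0.21 for Rsad2, -10.05 ± 0.16 for Ifit1 and -9.24 ± 0.20 for Cmpk2. They were -8.29 ± 0.14 for Iigp1, -7.88 ± 0.11 for Ifi44, -7.57 ± 0.10 for Isg15 and -5.42 ± 0.12 for Irf7. Adjusted p ran from 5.04e-18 for Isg15 to 2.17e-14 for Cxcl10. Mx1 had 9536 reads in KO and 3 in KO + H-151, a ratio of 4283 (95% counting interval 1465 to 20774). Ifnb1 had 0 reads in KO + H-151, at least 29.2-fold below KO against a floor of 3 reads over the group. Of the cGAS-STING genes, 9 of 17 fell and 0 rose (9 and 1 adjusted over the list alone), with a median of -0.39 (camera adjusted p = 2.03e-05, adjusted p = 0.226 with an estimated correlation). Cgas fell from 45.6 ± 4.18 to 10.3 ± 1.45 (-2.05 ± 0.14), Sting1 from 72.2 ± 8.43 to 35.99 ± 3.22 (-0.98 ± 0.10) and Samhd1 to 80.5 ± 6.11 (-3.04 ± 0.07).

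Of 30 NF-kB targets and secreted factors, 21 fell and 2 rose (22 and 2 adjusted over the list alone), with a median of -1.05 (camera adjusted p = 4.49e-16, adjusted p = 0.371 with an estimated correlation). Ccl2 fell from 1757 ± 103 to 60.5 ± 18.7 (-4.87 ± 0.13), Ccl7 from 1775 ± 34.1 to 132 ± 33.4 (-3.77 ± 0.11), Ccl5 to 0.487 ± 0.512 (-7.79 ± 0.21) and Il6 to 2.55 ± 0.101 (-3.66 ± 0.14). The members that rose were Cxcl5, from 28.99 ± 3.44 to 172 ± 103 (2.39 ± 0.26), and Cxcl12 (0.85 ± 0.08), which were also members that had fallen in KO. Of 20 antigen presentation genes, 17 fell and 0 rose, also when adjusted over the list alone, with a median of -1.29 (camera adjusted p = 9.14e-14, adjusted p = 0.225 with an estimated correlation). Tap1 fell to 28.3 ± 2.60 (-2.97 ± 0.09), Psmb10 to 33.04 ± 4.10 (-2.23 ± 0.10) and Psmb8 by 2.57 ± 0.11. The members that did not pass were the 3 chaperones that had fallen in KO, Calr (-0.00 ± 0.09; 0.30 and past the test under quantile normalization), Canx (0.02 ± 0.07) and Pdia3 (0.06 ± 0.11).

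All 16 macrophage and immune markers rose with H-151, with a median of 1.14 (camera adjusted p = 5.92e-10, adjusted p = 0.371 with an estimated correlation). Tyrobp, a signalling adaptor of myeloid cells, rose from 42.6 ± 1.64 to 114 ± 4.43 (1.40 ± 0.08), Csf1r, the receptor for macrophage colony-stimulating factor, from 25.1 ± 0.583 to 74.7 ± 2.54 (1.54 ± 0.09) and Lyz2 by 1.23 ± 0.10. All 10 adipocyte markers rose, with a median of 1.52 (camera adjusted p = 2.12e-09, adjusted p = 0.371 with an estimated correlation): Lpl by 1.51 ± 0.09, the fatty acid transporter Cd36 from 24.3 ± 2.02 to 94.5 ± 6.54 (1.92 ± 0.10) and the hormone gene Adipoq from 42.6 ± 2.56 to 132 ± 19.5 (1.60 ± 0.10). Among melanocyte and Schwann markers 2 (Dct†, Mbp) rose and 4 fell of 11. Those that fell included Sox10, the transcription factor of neural crest derivatives, from 45.1 ± 3.98 to 3.20 ± 0.371 (-3.46 ± 0.16), Cdh19 (-3.28 ± 0.23) and Erbb3, named after its value was seen. The list's mean was -0.85 and its median -0.00, a median that changed sign between scalings (camera adjusted p = 0.0394, adjusted p = 0.525 with an estimated correlation). The call was lost without a trend in the prior variance (adjusted p = 0.0704) or without KO + H-151 replicate 2 (adjusted p = 0.0514).

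Most matrix genes fell in the same libraries in which the macrophage and adipocyte markers rose. Of 47 genes of fibrillar matrix and its crosslinking, 34 fell and 5 (Dcn†, Lum†, Mfap2†, Ogn†, Thbs1†) rose (35 and 5 adjusted over the list alone), with a median of -0.49 (camera adjusted p = 5.62e-08, adjusted p = 0.328 with an estimated correlation). Elastin (Eln) fell from 116 ± 10.8 to 16.4 ± 2.36 (-2.75 ± 0.10), the crosslinking enzyme Loxl3 from 352 ± 13.8 to 93.3 ± 6.24 (-1.91 ± 0.07) and Col11a1 from 112 ± 0.658 to 43.4 ± 1.46 (-1.35 ± 0.07). Immediate early genes counted 4 (Btg2†, Dusp1†, Fosl2, Jund) up and 15 down of 23, with a median of -0.74 (camera adjusted p = 0.000578, adjusted p = 0.225 with an estimated correlation): Klf4 fell from 328 ± 6.50 to 79.5 ± 1.33 (-2.03 ± 0.07) and Jun from 352 ± 1.01 to 145 ± 1.46 (-1.27 ± 0.06). Of TGF-beta response genes 14 fell and 3 (Id1, Id2, Ski†) rose of 23, with a median of -0.52 (camera adjusted p = 0.000642, adjusted p = 0.377 with an estimated correlation, 3 up and 16 down adjusted over the list alone). They included Bambi, a decoy receptor of the pathway, which fell from 82.3 ± 15.9 to 6.23 ± 0.0573 (-3.51 ± 0.14), while Id2 rose by 1.28 ± 0.07.

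Genes of several metabolic lists rose beside the macrophage and adipocyte markers. Of the NRF2 antioxidant genes, 15 rose and 1 fell of 20, with a median of 0.45 (camera adjusted p = 0.000905, adjusted p = 0.225 with an estimated correlation, 16 up and 2 down adjusted over the list alone). The glutathione transferase Gstm1 rose from 84.9 ± 1.21 to 200.5 ± 7.16 (1.23 ± 0.07) and ferritin heavy chain (Fth1) from 2272 ± 9.51 to 4252 ± 28.8 (0.90 ± 0.07). The cystine transporter Slc7a11 fell from 14.4 ± 1.81 to 2.78 ± 0.139 (-2.02 ± 0.17). Of 25 sterol synthesis genes, 17 rose and 1 fell (19 and 1 adjusted over the list alone), with a median of 0.43 (camera adjusted p = 0.00248, adjusted p = 0.525 with an estimated correlation), a call lost with fry (adjusted p = 0.0786). Hmgcs1, an early enzyme of the pathway, rose from 343 ± 24.4 to 556 ± 33.5 (0.70 ± 0.09). Of fatty acid synthesis and lipid storage genes 11 rose and 1 (Cebpd) fell of 20, with a median of 0.37 (camera adjusted p = 0.00515, adjusted p = 0.226 with an estimated correlation, 12 up and 1 down adjusted over the list alone). They included the adipogenic transcription factor Cebpa (1.57 ± 0.09) and the desaturase Scd1, from 295 ± 4.64 to 457 ± 0.636 (0.63 ± 0.06).

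The largest rises with H-151 were those of G0s2, from 11.9 ± 0.308 to 111 ± 7.51 (3.12 ± 0.09), Fam43a (2.89 ± 0.10), Ppp1r3c (2.86 ± 0.16) and the carbonic anhydrase Car3, from 15.8 ± 0.0580 to 118 ± 49.2 (2.77 ± 0.20). Cxcl5, given above, Lyve1 (2.30 ± 0.25), a hyaluronan receptor of lymphatic endothelium and some macrophages, the Wnt agonist Rspo2 (2.19 ± 0.10), Gas1 (2.17 ± 0.07) and the vascular ligand Angpt2 (2.16 ± 0.22) followed. Targets of YAP and TAZ were not called with H-151: 5 (Ajuba, Amotl2, Arhgef17, Asap1, Nuak2†) rose and 11 fell of 22 (5 and 12 adjusted over the list alone), with a median of -0.38 (camera adjusted p = 0.0614, adjusted p = 0.289 with an estimated correlation). The list did pass without KO replicate 2 (adjusted p = 0.0374) or without KO + H-151 replicate 1 (0.0397) or 2 (0.0329), with DESeq2 on the recovered reads (0.0471) and with fry (0.000637). Ccn2 fell from 977 ± 142 to 454 ± 132 (-1.13 ± 0.14) and Ccn1 from 173 ± 26.6 to 111 ± 8.37 (-0.64 ± 0.09).

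With H-151, 2643 genes were higher and 2923 lower than in KO (limma, adjusted p threshold 0.05), of which 429 and 867 changed at least 2-fold and 0 and 77 at least 16-fold. The edgeR test on recovered reads gave 2614 and 2899, and DESeq2 1813 and 2519. Total-count scaling gave 4769 and 1930, and with a filter on a mean of 10 the higher genes were 1676. The share of higher genes among those changed was 47.5% as deposited, 51.3% under median scaling, 61.9% under quantile normalization and 71.2% under total-count scaling, which moved the median log2 change of all genes from 0.02 to 0.18. No control cells received H-151 in these 6 libraries, so an effect of the compound in cells with YAP and TAZ was not measured.

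The effects of KO and of H-151 were then set against each other gene by gene. Of the 2483 genes higher in KO, 1852 were lower with H-151, and of the 1938 genes lower in KO, 1179 were higher with H-151. Independent lists of the same lengths would share 532 and 375. In 100 simulations of unchanged groups on shared KO libraries the counts averaged 0.05 and 0.04. Groups without change give almost no calls in either comparison, so these averages cannot show how much of the overlap comes from sharing the libraries. Only 82 genes were higher in both comparisons and 80 lower in both. Across genes, which are not independent replicates, the log2 changes had a Pearson correlation of -0.87 (simulated -0.50) and a covariance of -0.469 (simulated -0.0112, difference -0.458). Each comparison used the same 2 KO libraries, so part of the excess over independent lists may come from sharing them. With KO replicate 1 set against control and KO + H-151 against KO replicate 2, 1336 genes were higher then lower and 568 lower then higher, against 289 and 149 for independent lists, with a covariance of -0.457. With the KO libraries exchanged the counts were 1356 and 552, against 291 and 148, with a covariance of -0.457. These 2 fits, chosen after the data were seen, assume that a lone library varies like the other groups. The balance of the 2 counts turned under quantile normalization (1467 higher then lower, 1794 lower then higher) and total-count scaling (1338 and 2650). DESeq2 gave 1590 and 723, and a filter on a mean of 10 gave 1380 and 766. The lower-then-higher count was 781 without control replicate 1, and 719 and 705 without KO replicates 1 and 2.

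Among the 779 genes at least 2-fold higher in KO, 757 (97.2%) fell with H-151, and among the 207 at least 2-fold lower, 171 (82.6%) rose. The genes with the largest sum of both changes were Cxcl10, Rsad2, Cmpk2, Ifit1, Mx1, Cxcl9, Oasl1, Iigp1, Gbp5 and Ccl5, all interferon-inducible. Of the 53 interferon-stimulated genes that rose in KO, 53 fell with H-151, 40 of them below control and 2 staying above it. Genes lower in KO that returned included Zfp703, from 43.1 ± 4.14 back to 184 ± 0.939 against 184 ± 8.34 in control, and Fam43a, back to 94.5 ± 6.77 against 83.9 ± 8.61. In contrast, Wwtr1 and Rps2 stayed low, with Rps2 at 74.8 ± 2.81 in KO + H-151. They were not the only ones. Of the 207 genes at least 2-fold lower in KO, 85 were still called below control in KO + H-151, 12 were above it and 110 were not called. The median reversal of these 207 genes was 74.6%.

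**Figure D2:**
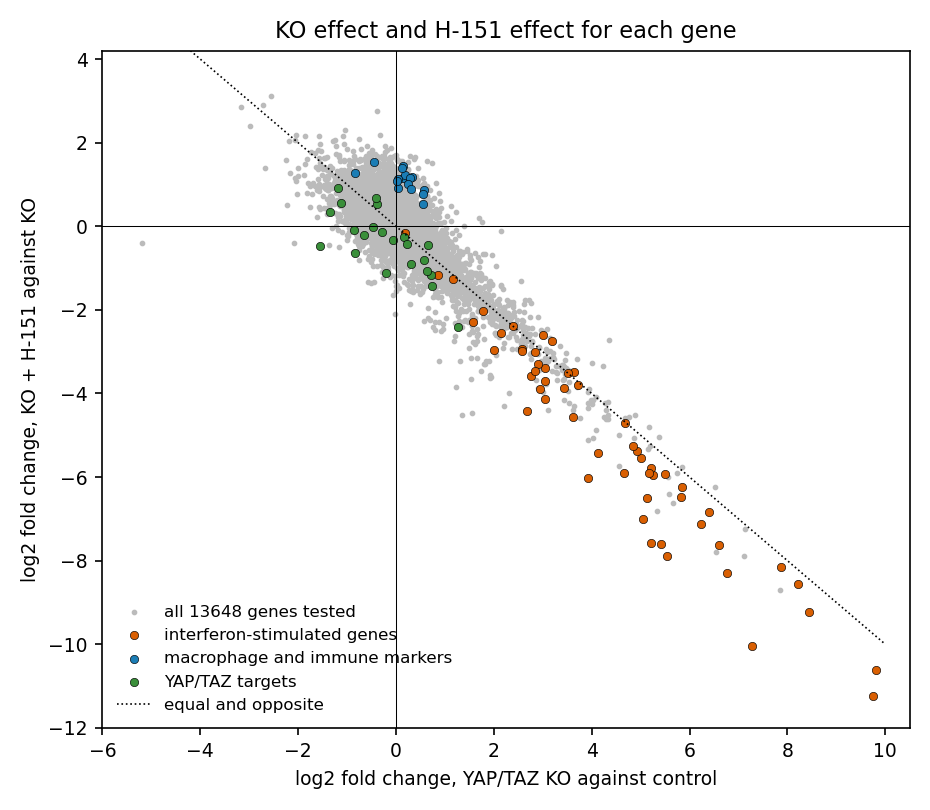
Log2 fold change of KO against control (horizontal axis) and of KO + H-151 against KO (vertical axis) for the 13648 genes tested, with interferon-stimulated genes, macrophage and immune markers and YAP/TAZ targets coloured. Most interferon-stimulated genes lie below the dotted line of equal and opposite change, and the macrophage markers lie above 0 on the vertical axis with KO effects between -0.84 and 0.56.

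The comparison of KO + H-151 with control shows how KO cells under the inhibitor differed from control. Of the 2483 genes higher in KO, 507 were higher than control here too and 324 were lower. Of the 1938 genes lower in KO, 477 were lower here too and 118 were higher. The interferon-stimulated gene Ifit1 lay below control, at 12.02 ± 4.53 against 86.5 ± 16.2, and so did the mitotic kinase gene Cdk1, at 48.8 ± 2.10 against 84.8 ± 3.65. Ccn1 stood at 111 ± 8.37 against 307 ± 4.82 in control, and Fabp4, a fatty acid carrier of adipocytes and macrophages, at 1177 ± 451 against 336 ± 81.6. Hmgcs1 was higher, and Hspa5 and the lactate dehydrogenase gene Ldha were lower.

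Of 54 interferon-stimulated genes, 40 were lower and 2 higher than in control, also when adjusted over the list alone, with a median of -0.59 (camera adjusted p = 5.59e-32, adjusted p = 0.105 with an estimated correlation); with Mx1, which had 3 reads in KO + H-151, at its ratio of reads, the median was -0.63. The 2 higher members were Slfn2 and Slfn5, named after their values were seen. Ifit1 differed by -2.78 ± 0.16, Isg15 by -2.37 ± 0.10, Rtp4 by -2.10 ± 0.08, Ifi44 by -2.33 ± 0.11 and Irf7 by -1.29 ± 0.12. Cgas (0.04 ± 0.14, adjusted p = 0.883) and Sting1 (0.00 ± 0.10, adjusted p = 0.992) did not pass, and Il6 was lower, at 2.55 ± 0.101 against 14.5 ± 0.486 (-2.12 ± 0.14). Of the NF-kB and secreted factors 4 (Ccl8, Il1rn†, Tnf†, Tnfaip2†) were higher and 10 lower of 30, with a median of -0.18 (camera adjusted p = 0.0284, adjusted p = 0.728 with an estimated correlation, 5 up and 10 down adjusted over the list alone). That call was lost with only the 2 groups in the fit (adjusted p = 0.0508), with DESeq2 (0.175), with fry (0.269), without control replicate 1 (0.122) and without KO + H-151 replicate 2 (0.409).

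Of 22 targets of YAP and TAZ, 14 were lower and 1 higher than in control (16 and 1 adjusted over the list alone), with a median of -0.47 (camera adjusted p = 1.2e-11, adjusted p = 0.105 with an estimated correlation). Ccn1 differed by -1.47 ± 0.09, Ankrd1 by -2.03 ± 0.20, Ccn2 by -1.34 ± 0.14 and Amotl2 by -0.999 ± 0.07. The 1 higher member was Asap1†, named after its value was seen. Mitosis genes were lower in 32 of 34 cases and higher in 0, with a median of -0.64 (camera adjusted p = 9.03e-15, adjusted p = 0.312 with an estimated correlation, 0 up and 34 down adjusted over the list alone), among them Cdk1 (-0.79 ± 0.08) and Prc1 (-0.90 ± 0.10). DNA replication genes counted 1 (E2f1†) higher and 13 lower of 32, with a median of -0.28 (camera adjusted p = 0.000628, adjusted p = 0.244 with an estimated correlation).

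Macrophage markers were higher in 15 of 16 cases, with a median of 1.28 (camera adjusted p = 1.1e-39, adjusted p = 0.226 with an estimated correlation, 16 up and 0 down adjusted over the list alone). Adipocyte markers were higher in 10 of 10, with a median of 1.41 (camera adjusted p = 1.88e-23, adjusted p = 0.226 with an estimated correlation). Tyrobp stood at 114 ± 4.43 against 38.9 ± 1.34 (1.52 ± 0.08) and Cd36 at 94.5 ± 6.54 against 28.6 ± 1.66 (1.69 ± 0.10). Beside them, sterol synthesis genes were higher in 24 of 25 cases, with a median of 0.81 (camera adjusted p = 4.16e-22, adjusted p = 0.279 with an estimated correlation), Hmgcs1 by 0.92 ± 0.09 and Dhcr7 by 1.03 ± 0.11. NRF2 genes were higher in 18 and lower in 1 (Slc7a11) of 20 (median 0.43, camera adjusted p = 1.09e-11, adjusted p = 0.105 with an estimated correlation). Lipid synthesis and storage genes were higher in 14 and lower in 1 (Cebpd) of 20 (median 0.51, camera adjusted p = 5.97e-10, adjusted p = 0.105 with an estimated correlation, 15 up and 2 down adjusted over the list alone). Lysosome and autophagy genes were higher in 17 and lower in 0 of 26 (median 0.31, camera adjusted p = 7.4e-10, adjusted p = 0.105 with an estimated correlation, 18 up and 0 down adjusted over the list alone). The lysosomal proteases Ctsb (0.88 ± 0.07) and Ctsd (0.83 ± 0.07), which macrophages also express highly, were among them.

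Fibrillar matrix genes were lower in 30 and higher in 3 (Col15a1†, Col6a3, Lum) of 47 cases (median -0.42, camera adjusted p = 1.95e-20, adjusted p = 0.226 with an estimated correlation, 4 up and 32 down adjusted over the list alone). Eln stood at 16.4 ± 2.36 against 50.3 ± 3.17 (-1.56 ± 0.10) and Col11a1 at 43.4 ± 1.46 against 161 ± 10.1 (-1.87 ± 0.07). Contractile genes were lower in 17 and higher in 0 of 30 (median -0.32, camera adjusted p = 8.07e-08, adjusted p = 0.312 with an estimated correlation, 0 up and 19 down adjusted over the list alone). TGF-beta response genes were lower in 13 and higher in 2 (Id2, Tgfb1†) of 23 (median -0.35, camera adjusted p = 3.74e-09, adjusted p = 0.279 with an estimated correlation, 3 up and 14 down adjusted over the list alone). Unfolded protein response genes were lower in 25 and higher in 1 (Atf3) of 28 (median -0.56, camera adjusted p = 3.29e-16, adjusted p = 0.244 with an estimated correlation), with Hspa5 at 1154 ± 1.53 against 2439.8 ± 142 (-1.08 ± 0.07). Hypoxia and glycolysis genes were lower in 18 and higher in 0 of 25 (median -0.48, camera adjusted p = 7.44e-14, adjusted p = 0.202 with an estimated correlation, 0 up and 20 down adjusted over the list alone), with Pdk1 at -0.89 ± 0.09 and Ldha at -0.63 ± 0.06.

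Shifts from control were called in 7 further lists. Immediate early genes were lower in 14 and higher in 1 (Dusp6) of 23 (median -0.40, camera adjusted p = 3.72e-05, adjusted p = 0.105 with an estimated correlation, 1 up and 15 down adjusted over the list alone). Ribosomal protein genes were lower in 12 and higher in 0 of 30 (median -0.21, camera adjusted p = 1.93e-07, adjusted p = 0.272 with an estimated correlation, 0 up and 14 down adjusted over the list alone), and Wnt signalling genes in 8 and 3 (Dkk3, Lef1†, Wif1†) of 19 (median -0.20, camera adjusted p = 0.000236, adjusted p = 0.221 with an estimated correlation, 3 up and 9 down adjusted over the list alone). Pericyte markers were lower in 3 (Mcam, Ndufa4l2, Notch3†) and higher in 0 of 7 (median -0.31, camera adjusted p = 0.00264, adjusted p = 0.202 with an estimated correlation). Mitochondrially encoded transcripts were higher in 6 and lower in 1 (mt-Nd6†) of 7 (median 0.47, camera adjusted p = 0.00175, adjusted p = 0.272 with an estimated correlation). Nuclear oxidative phosphorylation genes were higher in 6 and lower in 0 of 29 (median 0.13, camera adjusted p = 0.00781, adjusted p = 0.312 with an estimated correlation, 8 up and 0 down adjusted over the list alone). Secreted proteases and their inhibitors counted 4 (Ctsk, Mmp11, Mmp2†, Plau) higher and 8 lower of 22, with a median of 0.03 and a mean of -0.17 that differ in sign, and were called down (camera adjusted p = 0.000674, adjusted p = 0.609 with an estimated correlation). MHC class I genes (7 higher and 3 (Calr, Canx†, Pdia3†) lower of 20, 9 and 3 adjusted over the list alone, median 0.19, adjusted p = 0.159) were called without control replicate 1 (adjusted p = 0.0248) and with fry (0.0471). The call of Canx in this comparison (adjusted p = 0.0469) was lost under median scaling (adjusted p = 0.0518), quantile normalization (0.216) and total-count scaling (0.0616). It was lost too with only the 2 groups in the fit (0.0984), without a trend (0.206), with edgeR (0.0505) and with DESeq2 (0.05704).

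The largest rises over control were those of Car3 (2.37 ± 0.20), the matrix protein gene Sparcl1 (27.9 ± 1.45 against 5.09 ± 0.144, 2.25 ± 0.14), Gpd1 (2.20 ± 0.18), the clock gene Arntl2 (2.03 ± 0.20) and Ebi3 (1.97 ± 0.22). Below control, after Wwtr1, large differences were those of Pcdh20 (-3.17 ± 0.16), Moxd1 (-2.62 ± 0.18) and Rps2 (-2.48 ± 0.07). In total 1570 genes were higher and 1562 lower than in control (limma, adjusted p threshold 0.05), 253 and 168 of them at least 2-fold, and edgeR gave 1626 and 1585, DESeq2 1100 and 1215. Without a trend in the prior variance 937 genes were lower. Without control replicate 2 the counts were 951 and 924. Across the scalings, the share of higher genes among those changed lay between 50.1% as deposited and 52.9% under total-count scaling. With DESeq2, lower genes outnumbered higher ones. Cre, the loss of YAP and TAZ and H-151 all differ between these groups and cannot be separated.

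**Figure D3:**
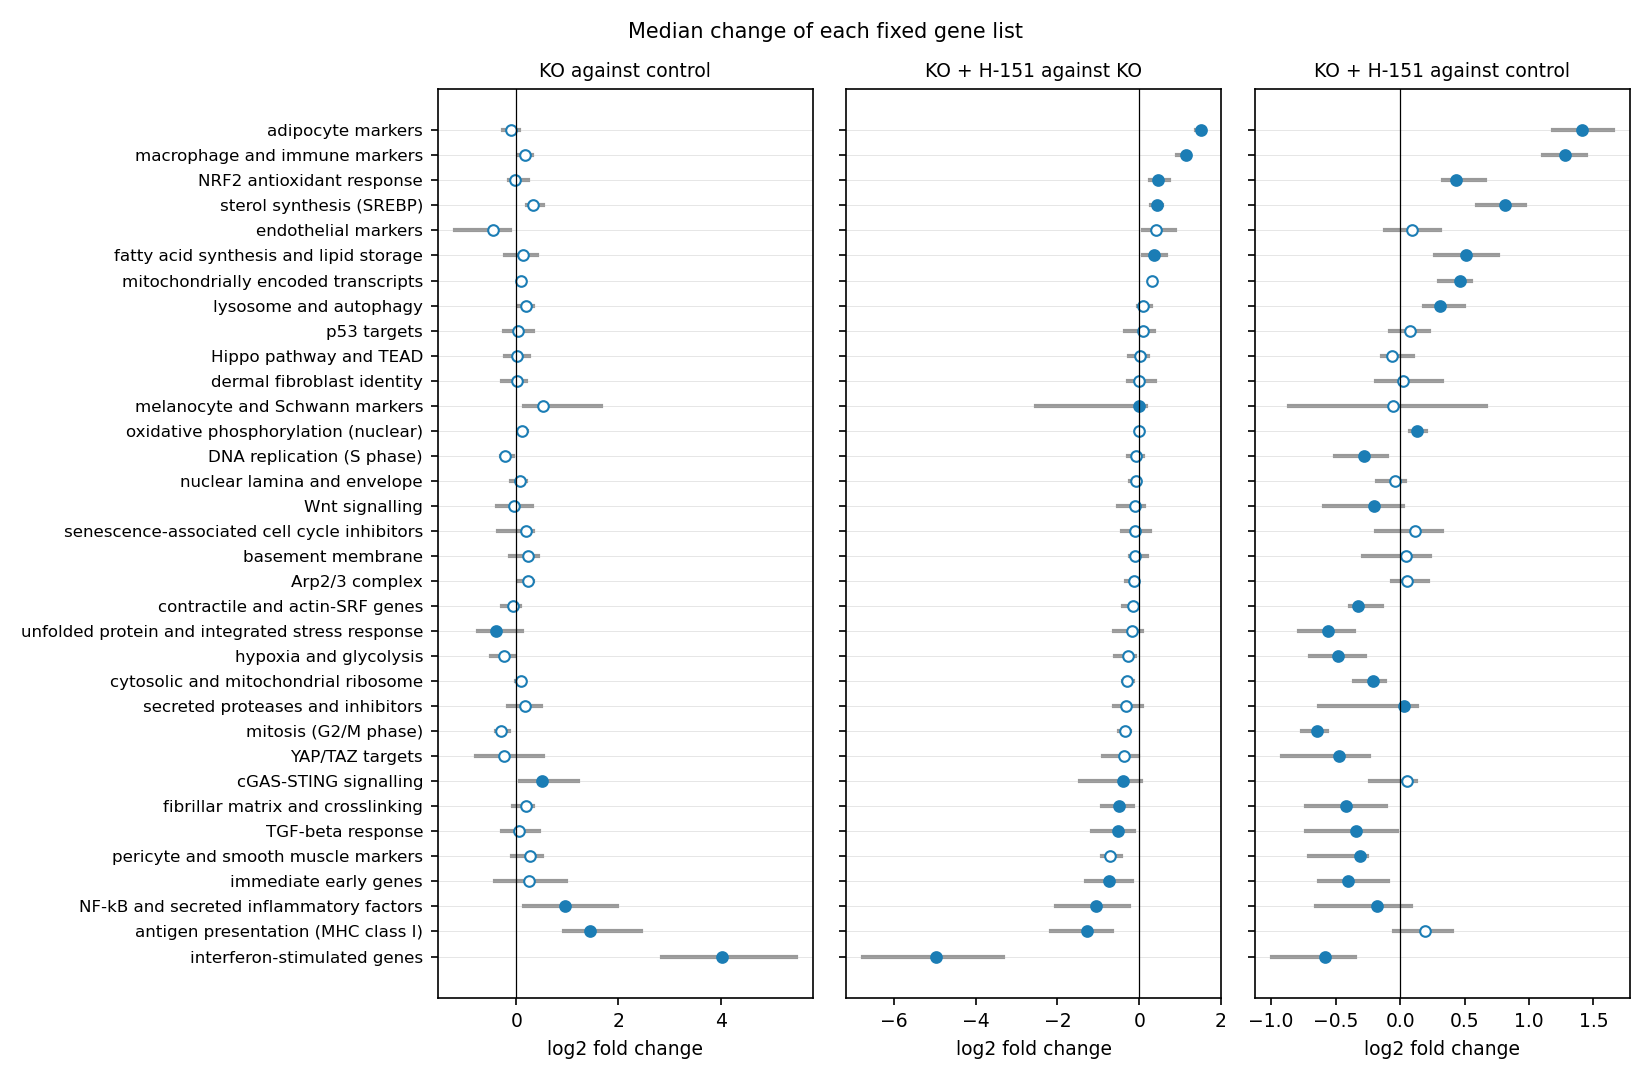
Median log2 fold change of the members of each of the 34 fixed gene lists in the 3 comparisons, with a bar from the lower to the upper quartile; filled points passed the camera test with the preset correlation. Interferon-stimulated genes had medians of 4.03, -4.98 and -0.59 from left to right, and macrophage markers 0.17, 1.14 and 1.28.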

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

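Total-count scaling, the crossed replicate term, the split KO libraries and the overlap without the interferon-stimulated list were chosen after seeing the data. The other alternatives were planned. Counts, medians and the correlation were recomputed for the 3 comparisons and for the overlap. Compared with the values as reported, 256 kept their direction and their side of the threshold or stayed within 1.5 times, 31 moved further, 3 tests of the interferon-stimulated list were no longer past the threshold and 1 of the YAP/TAZ targets newly was. The mean filter of 10, by testing fewer genes, gave 1266 lower genes in KO, 1676 higher with H-151 and 766 lower in KO and higher with H-151. Quantile normalization gave 2987 lower in KO and 1794 lower then higher. Without a trend in the prior variance, 937 genes were lower in KO + H-151 than in control. DESeq2 gave 1217 lower in KO and 723 lower then higher. A 2-fold minimum, which removes smaller changes by construction, gave 779 and 207 (KO), 429 and 867 (H-151) and 253 and 168 (KO + H-151 against control). Total-count scaling gave 4054 lower in KO, 4769 higher and 1930 lower with H-151, and 2650 lower then higher. With the KO libraries split, 568 and 552 genes were lower then higher. Except where stated, the cause was not tested. With an estimated correlation, a test that rests on the 3 residual degrees of freedom, 0 of the 34 lists were called. The calls lost there included those of the interferon-stimulated genes (medians 4.03, -4.98 and -0.59, adjusted p = 0.131, 0.143 and 0.105). Fry called 68 list tests, among them the YAP/TAZ targets in KO (median -0.25, adjusted p = 0.00371), and lost 3 of those reported. Cdkn1a turned from 0.23 to -0.027 under quantile normalization, where it was not past the threshold, and Calr with H-151 turned from -0.00, not past the threshold, to 0.30, past it. Of 262 gene values named, 254 were past the threshold; 202 of these kept their direction and side in each alternative that tested them and 52 lost their call at least once, while 35 of the 262 fell under the mean filter of 10 and have no value there.

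Leaving out each library leaves a group with 1 library, which is assumed to vary like the other groups. Over the 6 such fits, KO against control gave 1782 to 2718 higher and 1165 to 2186 lower genes, H-151 against KO 1776 to 2536 higher and 2200 to 2840 lower, and KO + H-151 against control 951 to 1373 higher and 924 to 1499 lower. The overlap ran from 1390 to 1881 (higher then lower) and from 705 to 1089 (lower then higher), and the correlation from -0.87 to -0.85. Lists called ran from 42 to 44. The median of YAP/TAZ targets in KO ran from -0.26 to -0.23, and that of interferon-stimulated genes from 3.99 to 4.06, from -5.06 to -4.91 and from -0.65 to -0.45.

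Genes named that lost their call without a library are listed with the adjusted p of that fit. Without control replicate 1: KO against control Cd14 0.0554, Cdkn1a 0.123, Ctss 0.0776, Egfl7 0.0719, Lmnb1 0.0577, Lpl 0.0987, Mbp 0.277, Mphosph8 0.0519, Nfil3 0.175, Rora 0.147, Sesn1 0.157, Trib3 0.0994; KO + H-151 against control Asap1 0.0640, E2f1 0.216, Lef1 0.213, Mmp2 0.0650, Notch3 0.181, Tgfb1 0.0607, Tnf 0.09998. Without control replicate 2: KO against control Btg2 0.0936, C1qc 0.237, Canx 0.221, Dct 0.0686, Dnmt1 0.0901, Fcer1g 0.224, Kdr 0.0626, Lmnb1 0.155, Nlrx1 0.0677, Polk 0.2496, Rora 0.0606, Tlr5 0.0839, Uhrf1 0.329; KO + H-151 against control Canx 0.353, Col15a1 0.359, E2f1 0.0661, Il1rn 0.199, Mmp2 0.201, Pdia3 0.0688, Tnf 0.0774, Tnfaip2 0.0672, Wif1 0.287, mt-Nd6 0.0741. Without KO replicate 1: KO against control Btg2 0.139, C1qc 0.0937, Canx 0.0812, Cdkn1a 0.188, Ctss 0.139, Dnmt1 0.0670, Kdm1a 0.0807, Lmnb1 0.0946, Lpl 0.156, Mbp 0.103, Mphosph8 0.0700, Nfil3 0.102, Nlrx1 0.0755, Polk 0.224, Rora 0.142, Sesn1 0.0980, Tlr5 0.0636, Trib3 0.0800, Uhrf1 0.113; H-151 against KO Bax 0.182, Btg2 0.246, Dcn 0.198, Dusp1 0.0945, Lum 0.0863, Mfap2 0.313, Nlrx1 0.252, Ogn 0.175, Ski 0.127, Thbs1 0.223; KO + H-151 against control Canx 0.0972, Col15a1 0.0889, Mmp2 0.0694. Without KO replicate 2: KO against control C1qc 0.156, Canx 0.186, Dct 0.0804, Egfl7 0.119, Fcer1g 0.253, Lmnb1 0.206, Mbp 0.149, Nfil3 0.0955, Polk 0.0769, Rora 0.0899, Sesn1 0.106, Tlr5 0.0572, Trib3 0.124, Uhrf1 0.148; H-151 against KO Bax 0.0920, Dcn 0.166, Dct 0.0876, Dusp1 0.164, Nuak2 0.0681, Ski 0.0591, Thbs1 0.120; KO + H-151 against control Canx 0.0974, Col15a1 0.0902, Mmp2 0.0696. Without KO + H-151 replicate 1: H-151 against KO Btg2 0.203, Dcn 0.286, Dusp1 0.369, Mfap2 0.0817; KO + H-151 against control Canx 0.0902, Col15a1 0.296, E2f1 0.0685, Il1rn 0.0582, Lef1 0.144, Mmp2 0.284, Notch3 0.0718, Tnf 0.255, Wif1 0.0506, mt-Nd6 0.0721. Without KO + H-151 replicate 2: H-151 against KO Bax 0.392, Nlrx1 0.0846, Ski 0.0967, Thbs1 0.0893; KO + H-151 against control Canx 0.0530, E2f1 0.0837, Tgfb1 0.0605, Wif1 0.0650.

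The labels state no pairing of replicate numbers across groups. The correlations of replicate differences were -0.07 (control and KO), 0.15 (control and KO + H-151) and -0.13 (KO and KO + H-151). Over genes with a mean of at least 20 they were -0.18, 0.26 and -0.28. With the replicate block, 4317, 5463 and 3013 genes changed in the 3 comparisons, against 4421, 5566 and 3132 as reported; among the genes named and the lists, the call of Canx in KO + H-151 against control was lost (adjusted p = 0.0685). With the KO numbers crossed, the replicate block gave 5322, 6369 and 3998, and 45 list calls against 41. The lists newly called were mitosis in KO (camera adjusted p = 0.0449) and, with H-151, YAP/TAZ targets (0.0247), mitosis (0.0492) and ribosomal protein genes (0.0335).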

Other observations

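The gene groups added here (11 written, 10 with enough tested members) were chosen after the data were seen, and so were the tests of scaling, Cre, cell mixture and ROSA26, but not that of the second macrophage list. Some members also stand in the fixed lists: 4 cell death effectors, 2 negative regulators and 6 genes of ubiquitin-like modifiers and the proteasome. Zbp1 and Usp18, for example, are in the interferon-stimulated list, so these groups partly recount the same genes. Of 23 cell death effectors, 17 rose and 0 fell in KO (median 0.84, camera adjusted p = 6.24e-11, adjusted p = 0.0621 with an estimated correlation). With H-151, 14 fell and 3 (Bax†, Bcl2l11, Gsdme) rose (median -0.68, camera adjusted p = 1.77e-07, adjusted p = 0.126 with an estimated correlation). Casp4, the inflammatory caspase that binds lipopolysaccharide, rose by 4.03 ± 0.15, the necroptosis effector Mlkl by 2.13 ± 0.12 and Zbp1, a sensor of Z-form nucleic acid, by 2.94 ± 0.17. The death ligand Tnfsf10 had 0 reads in control and 575 in KO, at least 230.4-fold higher against a floor of 3 reads. Guanylate-binding and immunity-related GTPases, 7 of which are also in the fixed lists, rose in 15 of 15 cases (median 4.67, camera adjusted p = 2.59e-113, adjusted p = 0.108 with an estimated correlation). They fell in 15 of 15 cases with H-151 (median -5.54, camera adjusted p = 8.2e-112, adjusted p = 0.126 with an estimated correlation).

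Of 15 negative regulators of interferon and cytokine signalling, 10 rose and 1 fell in KO (median 0.91, camera adjusted p = 7.22e-17, adjusted p = 0.106 with an estimated correlation). They included Socs1 (8.93 ± 1.75 to 197 ± 4.41, 4.33 ± 0.12), the checkpoint ligand Cd274 (5.74 ± 0.16) and Usp18, which removes ISG15 from proteins (5.42 ± 0.13). The 1 that fell was Nlrx1†. With H-151, 11 fell and 3 (Nlrx1†, Ptpn6, Trim24) rose (median -1.02, camera adjusted p = 1.02e-14, adjusted p = 0.126 with an estimated correlation). Among genes of nucleic acid sensing and Toll-like receptor signalling, 8 rose and 3 (Irak2, Ticam1, Tlr5†) fell of 20 in KO (median 0.05, camera adjusted p = 2.3e-10, adjusted p = 0.520 with an estimated correlation): the RNA receptor Tlr3 rose by 3.70 ± 0.11 and Tlr2 by 3.06 ± 0.14, and the adaptor Ticam1 fell by 0.90 ± 0.14. Circadian clock genes (4 (Bhlhe41, Nfil3†, Nr1d2, Rora†) rose, 7 fell, of 19, adjusted p = 0.496) and genes that silence endogenous retroviruses (4 (Daxx, Dnmt3a, Kdm1a†, Morc3) rose, 3 (Dnmt1†, Mphosph8†, Uhrf1†) fell, of 19, adjusted p = 0.348) were not called. Genes of ubiquitin-like modifiers and the proteasome rose in 14 of 23 cases in KO (median 0.28, camera adjusted p = 4.48e-19, adjusted p = 0.183 with an estimated correlation) and fell in 15 with H-151 (median -0.43, camera adjusted p = 2.69e-22, adjusted p = 0.126 with an estimated correlation). Imprinted genes counted 1 (Peg10) up and 6 down of 18 in KO (median -0.24, camera adjusted p = 0.0442, adjusted p = 0.408 with an estimated correlation).

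Interferon-stimulated genes rose in every KO library over both control libraries in 53 of 54 cases. Library scaling as the whole cause is argued against by the lowest median over 4 scalings, 3.87. A response to DNA breaks made by active Cre, which the control lacks, stays open. The median of p53 targets was 0.036, but its members went both ways (11 rose, 5 fell), which decides nothing. The 11 include Tap1, also an antigen presentation gene, with the largest rise of the list (3.14). The loss of YAP and TAZ is confounded with Cre here.

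All 16 macrophage markers rose with H-151 (adjusted p = 0.371 with an estimated correlation). Scaling is argued against by the lowest median over 4 scalings, 1.14. Fewer fibroblasts as the only change, which would raise markers of every other cell type alike, are argued against by list medians that lay 2.24 apart. These were 1.14 (macrophage), 1.52 (adipocyte), 0.42 (endothelial), -0.00 (melanocyte and Schwann) and -0.73 (pericyte). The permutation p of that range was 0.00183 (100000 resamples), but it treats the 52 marker genes as independent and does not measure spread between cultures. Estimated correlations within lists were 0.607 (macrophage) and 0.562 (adipocyte). The dermal fibroblast identity list counted 7 up and 7 down of 20 with H-151 (median 0.002). Of 47 fibrillar matrix genes, 34 fell and 5 rose. Fewer fibroblasts together with a separate change in another cell type could give unequal medians too, so these values do not exclude that. More macrophages in the KO + H-151 cultures may account for the rise of the macrophage markers. Of a second macrophage list, 81.8% rose (18 of 22, 0 fell, camera adjusted p = 5.06e-10, adjusted p = 0.126 with an estimated correlation), with Trem2 at 1.62 ± 0.11. A smaller share of fibroblasts or a change within the macrophages would raise these genes too, so the list does not single out more macrophages. A change of expression within the macrophages present stays open, as untested.

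Of the 26 tested genes within 1 Mb of ROSA26 (Gt(ROSA)26Sor, chromosome 6, 113067428 to 113077244, GRCm38), Lmcd1, Oxtr and Rad18 changed alike, by at least 0.5 (log2), in both Cre-bearing groups, against 392 of 12968 genes (3.02%) in the genome. DNA flanking the Cre insertion cannot be told apart from other causes (Fisher exact p = 0.0426; permutation p at the locus 0.0519), since the insertion marks both groups. Chance clustering along the genome stays open. Among windows centred on a gene near the locus, the fullest for its size was that of Lmcd1, with 3 of 8 genes changed alike. A window as full as that arose somewhere in the genome with a permutation p = 0.755 (1000 permutations). Gt(ROSA)26Sor had 3 reads in control, 65 in KO (ratio 26.04, 95% counting interval 8.53 to 130) and 95 in KO + H-151 (ratio 28.2, 9.38 to 139).

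Rps2, which can share reads with processed copies, stood at 423 ± 6.001 in control, 98.6 ± 2.42 in KO and 74.8 ± 2.81 in KO + H-151.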
